A study of Caenorhabditis elegans with 18 samples.

How the data were processed

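RNA was sequenced from embryos of 6 Caenorhabditis elegans strains, with 3 libraries per strain. The strains were wild type (N2), rbm-5(n5119), rbm-5(n5132), uaf-1(n4588) and the double mutants of uaf-1(n4588) with each rbm-5 allele. Eggs were freed from synchronized adults by bleaching, and total RNA was extracted and treated with DNase before Illumina library preparation. The labels give a replicate number but do not say whether the 3 libraries of a strain came from separate cultures. The p-values therefore measure only the spread between these libraries.

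The deposited values are FPKM (fragments per kilobase of transcript, relative to the mapped fragments of the library), 1 list per library, as the file headers state. The authors mapped reads with TopHat2 2.0.12 and Bowtie2 to the WBcel235 assembly, per the submitters' processing notes. Locus names in the lists show that transcripts were assembled separately in each library. Each list gives events with the FPKM of the transcripts that hold them: transcript starts and ends, skipped exons, groups of adjacent skipped exons, retained introns and alternative exon ends. The assembler and the event caller are not named in the sources at hand, and no scaling between libraries is stated. Read counts were not at hand, so the depth of each library is unknown and no counting interval can be given. Of 20574 labels that name 1 gene, 17488 equalled a symbol of annotation release 115, 2221 matched a sequence name, 10 had been turned into dates by a spreadsheet and were resolved by position, and 855 had no match. No listed entry lay on the mitochondrial chromosome.

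The transcript level of a gene was the summed FPKM of the start events of loci that name this gene alone, analysed on the log2(FPKM + 1) scale. Splicing was analysed as log2((inclusion FPKM + 1) / (exclusion FPKM + 1)). Inclusion was the form with the exon, with the retained intron, or with the given exon end, and exclusion the other form or, for alternative exon ends, the rest of the locus. Because of the pseudocount, this ratio also moves with the level of a gene when 1 form is at 0 in every library. The share of inclusion, between 0 and 1, is given beside it. A gene or an event was tested where it was listed in at least 2 libraries of each strain of a contrast and had a mean of at least 1 FPKM, for an event over both forms together. Values listed at exactly 0 were kept, although they can be failed estimates: every library lists some ribosomal protein genes at 0 (4–9 per library, where 33–49 are listed). Genes with such values are reported as listed at 0.

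Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per strain over all 18 libraries and moderated statistics, with an intensity trend for expression and without one for splicing. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene or event was called at an adjusted p under 0.05. The contrasts were each single mutant against wild type, each double mutant against uaf-1(n4588) and against its rbm-5 single mutant, the rbm-5 alleles against each other, and an interaction per rbm-5 allele. The interaction is the uaf-1(n4588) effect in the rbm-5 mutant minus that in wild type. These contrasts, their tests, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. After the data had been seen, 3 averaged contrasts were added: uaf-1(n4588) over 3 backgrounds, rbm-5 mutations over alleles and backgrounds, and the interaction over alleles. The model was tested on simulated data, 1 set for genes and 1 for events. Changes of 4 sizes were added together, each size to 50 genes or events, in the libraries of uaf-1(n4588) only, which were then compared with wild type. For genes, 14% were recovered at a log2 change of 1, 46% at 2, 76% at 3 and 82% at 4, with 5 false calls. For events, 2%, 20%, 44% and 62% were recovered at the same sizes, with 2 false calls.

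The named genes were chosen by rule. The genes rbm-5, uaf-1, unc-93 and tos-1 came first. Then followed up to 10 rises and 10 falls per expression contrast among called genes whose libraries did not overlap and whose higher strain averaged at least 5 FPKM, up to 12 called events per splicing contrast with the largest change in share, 1 per gene, and up to 4 members per gene list. Where none passed, the 5 with the smallest p are given as values. Genes outside the rule are marked as chosen after their values were seen. Exact permutation tests, also two-sided, compared the number of listed events per library, with labels permuted within backgrounds and adjustment over the event types. The uaf-1(n4588) effect in an rbm-5 mutant was related to that in wild type by a slope through the origin across called items, set beside slopes of simulated data with equal effects. In the simulated data an item carried its averaged uaf-1(n4588) effect where the averaged contrast called it, and no effect elsewhere. The simulated range is therefore no reference for an item called in wild type but not in the averaged contrast.

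Of the 22 gene lists, 21 had at least 3 tested genes in a contrast, and the mitochondrially encoded list was not measured. Lists were tested with limma's camera on the moderated statistics with a preset correlation of 0.01, adjusted over 194 pairs of list and contrast. Camera with an estimated correlation, camera with the replicate number as a block, and fry need complete values and were run on the 4182 genes listed in all 18 libraries, which departs from the plan. The alternatives were a pseudocount of 0.1, no filter or a filter at 5 FPKM, libraries scaled to the same median, gene levels from end events or from the larger of start and end events, the replicate number as a block, a fit of only the libraries in a contrast, replicates 2 and 3 alone, and leaving out each library. The labels do not say what the replicate numbers stand for. In 2 comparisons all 3 pairs of same-numbered libraries had deviations from their strain means correlated above 0.1. These were uaf-1(n4588) with wild type (0.104–0.307) and the double mutant with n5132 with rbm-5(n5132) (0.188–0.414), and there the blocked value stands beside a result that it changes. An analysis of 3′ splice site sequences was planned, but no genome sequence was at hand. Tables and permutations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.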

Results

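The series compares gene expression between strains in embryos. Its title concerns how RBM-5, an RNA-binding protein, modifies alternative splicing that depends on the large subunit of U2AF. U2AF recognises 3′ splice sites. The gene uaf-1 encodes that subunit. There were 18 libraries, 3 for each of 6 strains, and each listed between 53772 and 55828 entries, of which 26.7–33.7% had an FPKM of 0. Each library held 21588–22161 transcript starts in 18997–19730 loci. Over all libraries, 9870 genes were listed singly in every library, as were 883 skipped exons, 241 retained introns and 1165 alternative exon ends. Read depth is unknown because only FPKM values were at hand. Spearman's correlation across genes, which are not independent, was 0.768–0.924 between libraries of a strain (median 0.845) and 0.689–0.914 between strains (median 0.851), so libraries of a strain were no more alike than others. The replicate 1 libraries stood apart in summed start FPKM, at 1.25e+06–2.07e+06. Their 10 highest start events held 21.3–43.7% of it, against 7.57–11.8% in replicates 2 and 3. Other libraries stood apart on the main axis of variation in expression (27.3% of variance). There, rbm-5(n5119) replicate 3 scored −72.8 and replicate 1 of its double mutant −56.6, against −29.7 to 50.9 elsewhere. These libraries also had the most entries at 0 (33.7% and 32.1%), and contrasts with n5119 include them. Values after ± are standard deviations over the libraries of a strain (n = 3 unless stated). SE is the standard error of a fitted log2 change, and coordinates refer to WBcel235.

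The mutated genes were transcribed in every strain. The level of uaf-1 (III:1062794–1076555) was 176 ± 47.8 FPKM in wild type and 98.8 ± 29.1 FPKM in uaf-1(n4588), a difference that did not pass the test (log2 −0.83, SE 0.25, adjusted p = 0.430). It was 206 ± 25.5 FPKM in rbm-5(n5119), 164 ± 8.61 in rbm-5(n5132), 156 ± 15.4 in the double mutant with n5119 and 176 ± 34.4 in that with n5132. The level of rbm-5 (I:6215727–6219912), from start events, was 32.2 ± 2.14 FPKM in wild type (n = 2) and 35.1 ± 25.6 FPKM in rbm-5(n5132), where 1 library at 64.6 FPKM raises the mean over 19.2 and 21.4 FPKM (log2 −0.10), and no contrast passed (lowest adjusted p = 0.805, for rbm-5 mutations averaged). End events of rbm-5 gave 38.6 ± 11 FPKM (n = 2) and 87.3 ± 17.8 FPKM in the same strains, a difference that did not pass when end events were fitted as an alternative. A retained intron of rbm-5 (I:6215987–6216059) was listed in all 3 rbm-5(n5132) libraries and in 2 of 3 libraries of its double mutant. Its share was 1 in each, and none of the other 13 libraries listed it. The listing was not tested, and transcript levels do not otherwise check which allele a library carries. Of the known targets, unc-93, a regulator of a muscle potassium channel, was at 5.65 FPKM in wild type and 3.02 FPKM in uaf-1(n4588) (log2 −0.89, adjusted p = 1). The gene tos-1 was at 70.2 ± 25 FPKM in wild type and 93.8 ± 40.2 FPKM in uaf-1(n4588) by start events (adjusted p = 1), but at 412 ± 139 and 98.9 ± 31.6 FPKM by end events, so the direction depends on the transcript end read. End events were fitted as an alternative, and the result for this gene is not given here. Its exon at V:9343501–9343567 had an inclusion share of 0.948 ± 0.091 in wild type and 0.536 ± 0.14 in uaf-1(n4588), which did not pass in that contrast (adjusted p = 0.185) but did on average over 3 backgrounds (log2 −4.32, adjusted p = 0.0376).

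**Figure D1:**
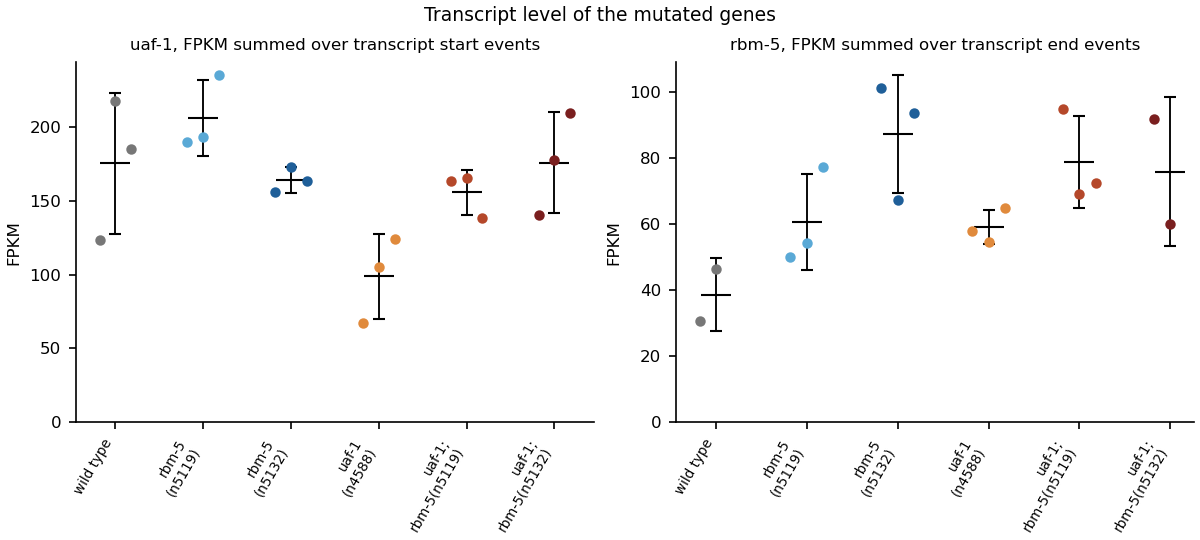
FPKM (y axis) of uaf-1 from start events and of rbm-5 from end events in each library (points) of the 6 strains (x axis), with the mean (long line) and standard deviation. The uaf-1(n4588) libraries lie between 67.1 and 124 FPKM for uaf-1, and rbm-5 has 2 values in wild type and in the double mutant with n5132.

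The comparison of uaf-1(n4588) with wild type asks which splicing choices depend on the U2AF large subunit. Exons and exon ends that wild-type embryos used were lost from transcripts of several genes. The exon of let-653 at IV:11888697–11888816, from a secreted protein that shapes the excretory duct, fell from a share of 0.899 ± 0.18 to 0 in each uaf-1(n4588) library (log2 −6.32, SE 0.75, adjusted p = 0.000404). An exon of tnt-3 (X:7938516–7938662), which encodes troponin T, fell from 0.601 ± 0.0083 to 0.0487 ± 0.084 (log2 −5.40, SE 0.91, adjusted p = 0.0104). An exon of sao-1 (V:13964759–13964821) fell from 0.333 ± 0.078 to 0 in each library (log2 −5.24, SE 0.46, adjusted p = 1.61e-05). The intron of D1054.9 at V:10787206–10787288 was retained at a share of 1 in each uaf-1(n4588) library against 0.0763 ± 0.13 in wild type (log2 7.66, SE 1.22, adjusted p = 0.00725).

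Most other called events were alternative 3′ ends of introns, that is, exons with an alternative acceptor. In the forkhead gene fkh-7, the shorter exon IV:5608369–5608444 had a share of 0 in each wild-type library and 0.405 ± 0.049 in uaf-1(n4588) (log2 4.82, SE 0.31, adjusted p = 4.53e-07). The longer exon that starts at 5608312 fell. The acceptor form of B0001.7 at IV:12152322–12152515 fell from 0.793 ± 0.22 to 0 in each library, and that of the neuropeptide gene flp-1 (IV:9145521–9145607) from 0.618 ± 0.079 to 0. That of the homeobox gene lim-4 (X:3870408–3870557) fell from 0.534 ± 0.15 to 0, and that of spe-48 (I:1953349–1953549) from 0.159 ± 0.041 to 0. Adjusted p for these 4 lay between 0.000385 and 0.0148. The chemoreceptor gene srh-2 gained the form V:732061–732169 (0.109 ± 0.19 to 0.821 ± 0.06, adjusted p = 0.0216). An alternative donor exon of pph-4.2, a protein phosphatase 4 catalytic subunit (III:12375580–12376226), fell from 1 in each library to 0.587 ± 0.28 (log2 −4.92, SE 0.89, adjusted p = 0.0182).

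In total, limma called 13 of 3072 tested events, 3 higher and 10 lower, in 11 genes. Of all tested events, 220 (7.16%) had an unadjusted p under 0.05. Where nothing changes, a share of about 0.05 of tests falls under that threshold, here and below. The libraries of the 2 strains did not overlap for any of the 13, where chance gives 10% of 3 against 3. Called items here and below were chosen by p in the same libraries, so separation adds no evidence of its own. A fit of only these 6 libraries called 22 events (7 shared with the 13), replicates 2 and 3 called 31 (10 shared), and leaving out 1 library gave 10–19. Calls ended without single libraries for srh-2 (uaf-1(n4588) replicate 1, log2 2.5, replicate 2, log2 2.99, or wild-type replicate 3, log2 2.32). So did those for flp-1 (uaf-1(n4588) replicate 1, −5.69) and tnt-3 (uaf-1(n4588) replicate 2, −4.84). The others were lim-4 (uaf-1(n4588) replicate 1, −3.92, or 2, −3.85, or wild-type replicate 1, −3.40) and pph-4.2 (uaf-1(n4588) replicate 1, −3.92, wild-type replicate 2, −4.30, or 3, −4.89).

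**Figure D2:**
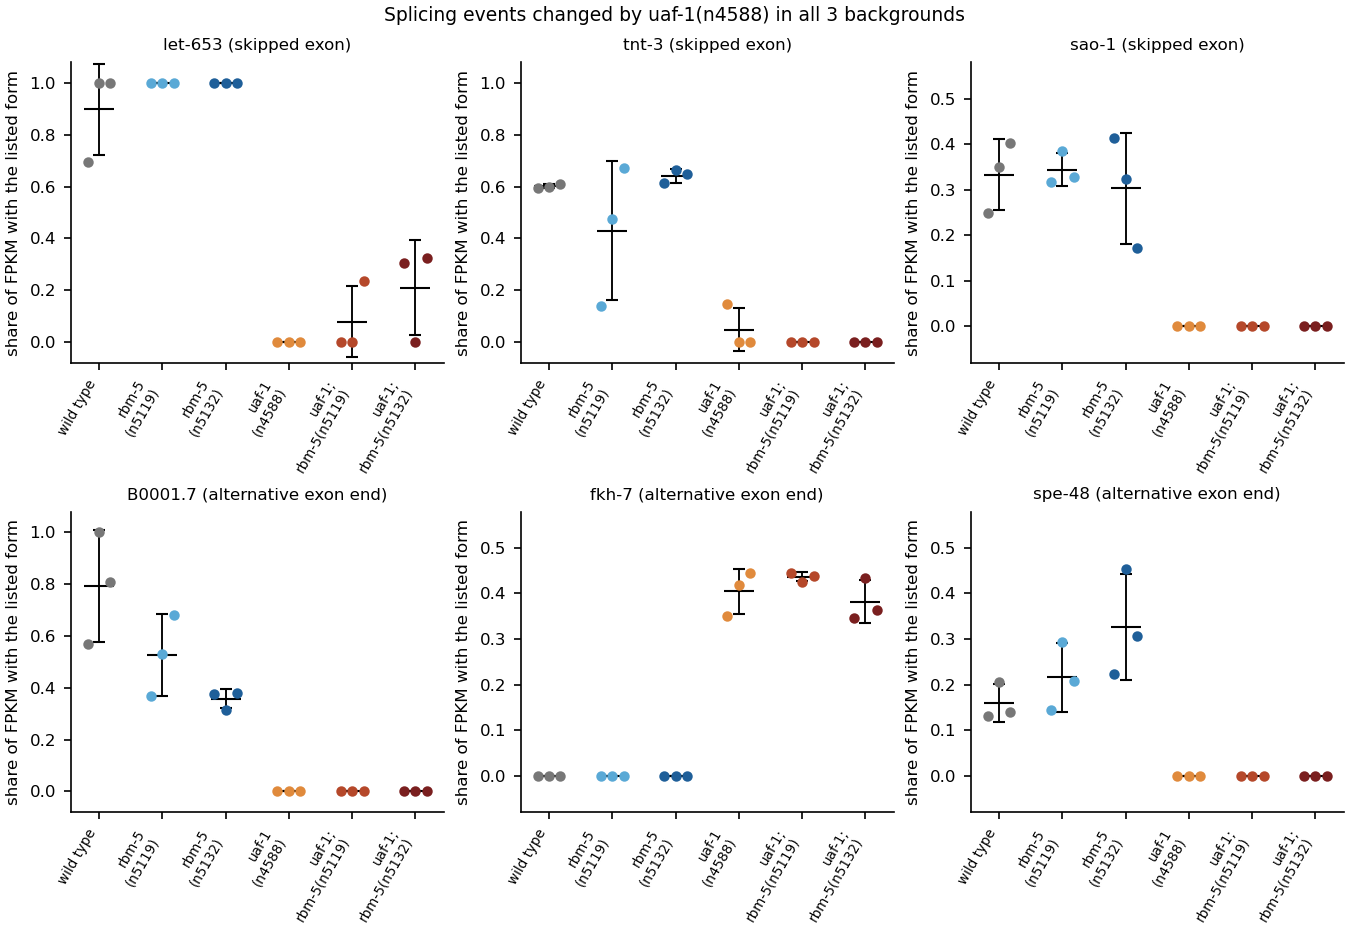
Share of FPKM with the listed form (y axis, 0 to 1; exon included, or the given alternative exon end) in each library (points) of the 6 strains (x axis), with the mean (long line) and standard deviation, for 6 genes with an event called for uaf-1(n4588) in all 3 backgrounds. In fkh-7 all 9 libraries without uaf-1(n4588) lie at 0, and in sao-1, spe-48 and B0001.7 all 9 libraries with it do.

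The same question in an rbm-5 mutant is answered by each double mutant against its rbm-5 single mutant. The events of let-653, tnt-3, sao-1, fkh-7, spe-48 and B0001.7 changed in the same direction there as in wild type. With n5119, the let-653 exon was at 1 in each single-mutant library and 0.0793 ± 0.14 in the double mutant (log2 −6.41, adjusted p = 0.000339), and with n5132 at 1 and 0.211 ± 0.18 (log2 −4.84, adjusted p = 0.00608). The new fkh-7 acceptor reached 0.437 ± 0.01 with n5119 (log2 5.22, adjusted p = 1.64e-07) and 0.382 ± 0.047 with n5132 (log2 4.66, adjusted p = 6.51e-07). With n5119, a pair of adjacent exons of pcyt-2.1, an enzyme of phosphatidylethanolamine synthesis (I:2081956–2082075), rose from 0 to 0.584 ± 0.082 (log2 6.15, SE 0.91, adjusted p = 0.00384). There, an intron of the ubiquilin gene ubql-1 (I:7022446–7022501) was spliced out more often, with retention falling from 1 in each library to 0.724 ± 0.047 (adjusted p = 0.00581). The exon of the riboflavin transporter gene rft-2 (V:4447028–4447066) rose from 0 to 0.304 ± 0.021 (adjusted p = 0.0411). Retention in Y106G6H.6 fell from 1 to 0.789 ± 0.059 (adjusted p = 0.0411) and in C05D11.8 from 1 to 0.597 ± 0.077 (adjusted p = 0.02). With n5132, retention of an intron of brd-1, the BARD1 homologue (III:6887378–6887421), rose from 0.214 ± 0.013 to 0.741 ± 0.08 (log2 3.23, SE 0.48, adjusted p = 0.00685).

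With n5119, 18 of 3020 events were called (6 higher, 12 lower, in 13 genes), and with n5132, 10 of 3101 (3 higher, 7 lower, in 7 genes), all 28 with libraries that did not overlap (chance 10%). Replicates 2 and 3 called 33 and 19, and leaving out rbm-5(n5119) replicate 1 gave 28 and rbm-5(n5132) replicate 3 gave 18. Of 23 events called in any of these 3 uaf-1(n4588) contrasts, 8 in 6 genes were called in all 3, and all 22 that were tested in all 3 had the same sign of log2 change. For the pph-4.2 form the values with n5119 and n5132 were far within their error (log2 −0.047 and −0.034, SE 0.89 for both), so its sign shows no change there. The calls of rft-2, Y106G6H.6 and C05D11.8 with n5119 ended without nearly any 1 library, as did that of B0001.7 with n5132 (log2 −4.48 to −3.83), which also ended with the replicate number as a block (log2 −4.19). That of tnt-3 with n5119 ended without rbm-5(n5119) replicate 2 (−4.67) or 3 (−4.13) or double-mutant replicate 2 (−4.79) or 3 (−4.56).

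Averaged over the 3 backgrounds, a contrast added after the data were seen, uaf-1(n4588) changed 71 of 2534 events in 53 genes (37 higher, 34 lower, 299 at an unadjusted p under 0.05). For 24 of them, all 9 libraries with uaf-1(n4588) lay outside the range of the 9 without it, where chance gives 0.00411%. By type, 19 of 819 skipped exons were called (8 more included, 11 less), 9 of 221 groups of adjacent exons (1 more, 8 less), 16 of 341 retained introns (11 more retained, 5 less), 27 of 1150 alternative exon ends and none of 3 groups of retained introns. Beside the genes above, a pair of exons of the glutamate receptor gene glr-2 fell (log2 −1.82, adjusted p = 0.00153), as did an acceptor form of bath-44 (log2 −4.28, adjusted p = 0.00123, from 0.502 ± 0.15 in wild type to 0.0959 ± 0.084) and an exon of F49E2.5 (log2 −3.55, adjusted p = 0.00649). Introns of lsy-2, a zinc finger gene (X:2091010–2091062), and ipla-3, a phospholipase gene (V:20727305–20727361), were retained more (log2 3.07 and 2.44, adjusted p = 0.00731 and 0.00265). Other settings gave 61–73 calls, and leaving out 1 library gave 54–69.

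Transcript levels of few genes differed between uaf-1(n4588) and wild type. E01G4.5 (II:13472401–13473995) rose from 27.3 ± 5.7 to 292 ± 36 FPKM (n = 2 in the mutant; log2 3.38, SE 0.33, adjusted p = 0.00163), and Y37E3.30 (I:2149825–2151826) from 40.7 ± 16 to 301 ± 11 FPKM (log2 2.92, SE 0.34, adjusted p = 0.00163). The transcription factor gene zip-11 (IV:3311276–3313189) rose from 4.54 ± 1.2 to 32.5 ± 8.8 FPKM (log2 2.58, adjusted p = 0.0185), the long noncoding RNA linc-8 (II:2501838–2503802) from 30 ± 3 to 121 ± 49 FPKM. F44E7.5 rose from 18.2 ± 14 to 151 ± 34 and the noncoding RNA Y116A8B.98 from 1.71 ± 0.37 to 8.45 ± 1.2 FPKM. These 3 had an adjusted p of 0.0211. On chromosome III, sna-3 (6202622–6206211) fell from 123 ± 19 to 47.9 ± 7.4 FPKM (log2 −1.34, SE 0.19, adjusted p = 0.00869). Also there, C46F11.4 (3657712–3664304) fell from 47.8 ± 5.5 to 15.1 ± 2.0 (adjusted p = 0.0211) and the amidohydrolase gene amdh-1 (6251811–6271283) from 18.1 ± 3.8 to 2.79 ± 0.24 (adjusted p = 0.0376). The gene uaf-1 lies on the same chromosome, and a sequence variant linked to it was not tested as a cause of these falls. The transporter gene abt-5, outside the naming rule and chosen after its values were seen, was at 2.64 ± 1.1 and 0.268 ± 0.12 FPKM (adjusted p = 0.0376).

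Another 4 called genes depended on values listed at 0 or on which transcript end was read. E01A2.1 was listed at 0 in each wild-type library and at 107, 75.0 and 89.9 FPKM in uaf-1(n4588) (adjusted p = 0.0211). F23D12.7 was listed at 0 and at 24.8 and 3.35 FPKM (adjusted p = 0.0376), but its end events were at 0 in every library that lists them. The NF-kappaB inhibitor homologue ikb-1 was listed at 0 in the 2 uaf-1(n4588) libraries that list it, but end events of the same libraries gave the opposite direction (log2 7.62). F02E9.5 was called (log2 3.01, adjusted p = 0.000794), but not with end events (log2 0.22, adjusted p = 1). In all, 14 of 8451 genes were called, 9 higher and 5 lower. All 14 had libraries that did not overlap (chance 10%), and 486 genes had an unadjusted p under 0.05. The count fell to 9 with libraries scaled to 1 median, to 6 with the contrast's libraries alone and to 9 with replicates 2 and 3. With the replicate number as a block it was 6: E01G4.5, Y37E3.30, zip-11, F44E7.5, F02E9.5 and sna-3. It was 7 without wild-type replicate 1, 3 without wild-type replicate 3, and 6, 5 and 5 without uaf-1(n4588) replicates 1, 2 and 3. E01G4.5 could be tested in 11 alternatives and Y37E3.30 in 14. Among these, their calls ended only in the fit of the contrast's own libraries (adjusted p = 0.0717 for both). That of sna-3 ended without wild-type replicate 3 (log2 −1.36) or uaf-1(n4588) replicate 2 (−1.30). The calls of zip-11 (log2 2.42 to 2.55), linc-8 (1.60 to 2.07), F44E7.5 (2.67 to 3.35), Y116A8B.98 (1.71 to 1.89), amdh-1 (−2.37 to −2.29), C46F11.4 (−1.68 to −1.50), abt-5 (−1.69 to −1.26) and E01A2.1 (6.38 to 6.63) each ended without any of several single libraries.

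**Figure D3:**
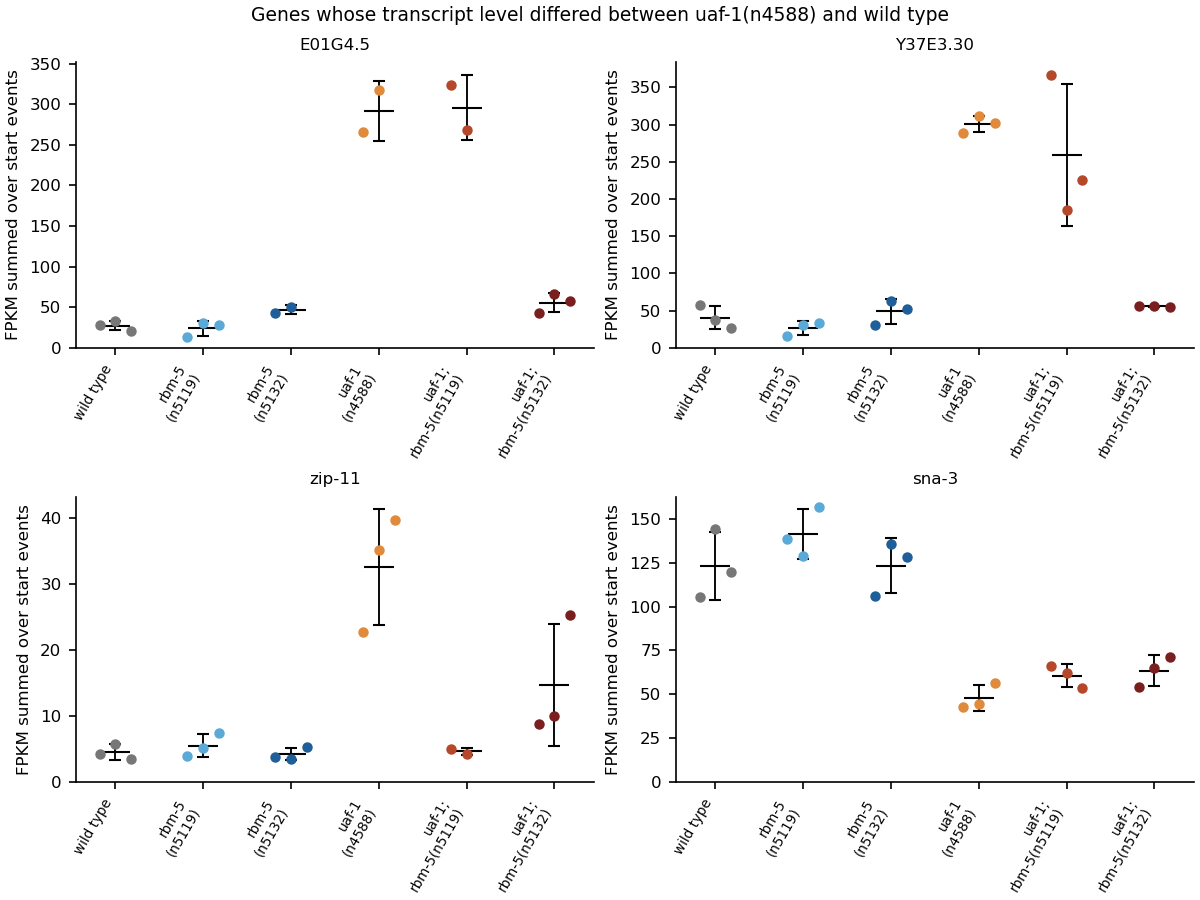
FPKM summed over start events (y axis) of E01G4.5, Y37E3.30, zip-11 and sna-3 in each library (points) of the 6 strains (x axis), with the mean (long line) and standard deviation. E01G4.5 and Y37E3.30 average 292 and 301 FPKM in uaf-1(n4588) but 55.6 and 56.1 FPKM in its double mutant with n5132, and sna-3 is at most 71.3 FPKM in all 9 libraries with uaf-1(n4588).

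In the rbm-5(n5119) background, uaf-1(n4588) raised E01G4.5 (24.3 ± 9.1 to 296 ± 40 FPKM, n = 2 in the double mutant, log2 3.62, SE 0.34, adjusted p = 0.00106) and Y37E3.30 (26.7 ± 9.5 to 259 ± 95 FPKM, log2 3.24, adjusted p = 0.00106). It lowered sna-3 (141 ± 14 to 60.7 ± 6.5 FPKM, log2 −1.21, adjusted p = 0.0186). It also raised F15D4.5 (5.24 ± 2.8 to 40.5 ± 5.7 FPKM, adjusted p = 0.017), the noncoding RNAs C38D9.13 (log2 3.67, adjusted p = 0.00106) and Y116A8B.98 (adjusted p = 0.043), and the F-box gene fbxc-25 (30.1 ± 10 to 73.9 ± 12 FPKM, adjusted p = 0.0496). K10D2.5 (log2 −6.40) and Y45G12B.3 (log2 3.68) had a strain listed at 0 throughout, as did C44B12.6, which lay outside the naming rule. In total 8 genes were higher and 2 lower of 8511 tested. All 10 had libraries that did not overlap (chance 10%), and 333 genes were at an unadjusted p under 0.05. The count was 3 without double-mutant replicate 2 and 4 without replicate 3, 17 with replicates 2 and 3, and 0 in the fit of the contrast's own libraries. Calls of sna-3 (log2 −1.23 to −1.12), F15D4.5 (2.63 to 2.90), Y116A8B.98 (1.82 to 1.97) and fbxc-25 (1.10 to 1.38) ended without any of several single libraries. In the rbm-5(n5132) background, 1 gene was called higher and 1 lower of 8378 (413 at an unadjusted p under 0.05), and leaving out double-mutant replicate 1 gave 5. Both had a strain listed at 0: C07D10.6 was at 109 and 139 FPKM in the double mutant by start events and 0 in the other strains (adjusted p = 1.14e-09). Its end events were at 348 FPKM in 1 uaf-1(n4588) library and at 289 and 421 FPKM in the double mutant with n5119, so the listing at 0 there depends on the transcript end read. Y45G12B.3 was listed at 0 in the double mutant (adjusted p = 0.0203), a call lost without any 1 rbm-5(n5132) library (log2 −3.96 to −3.63) and with the replicate number as a block (log2 −3.61, adjusted p = 0.0558).

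Averaged over backgrounds, 47 of 7160 genes were called (26 higher, 21 lower, 503 at an unadjusted p under 0.05). Of these, 17 had all 9 libraries with uaf-1(n4588) outside the range of the 9 without it (chance 0.00411%). Among these 17, F-box genes, whose products select proteins for ubiquitination, were higher: fbxc-25 (log2 1.04, SE 0.13, adjusted p = 0.00157), fbxa-143 (log2 1.22, adjusted p = 0.00283), fbxb-6 (1.19, 0.0077), fbxc-54 (0.96, 0.0044), fbxa-76 (0.88, 0.013) and fbxb-78 (0.58, 0.0165). H11L12.1 (log2 1.93), the lectin gene clec-266 (0.81) and ZC262.2 (0.56) were also higher. Lower were sna-3 (log2 −1.17, SE 0.11, adjusted p = 7.37e-05), F23F1.4 (−2.16), amdh-1 (−1.78), the glycine decarboxylase gene gldc-1 (−1.56), the acid phosphatase gene acp-5 (−1.01), the cell cycle kinase gene cdk-4 (−0.91, adjusted p = 0.00506), C30F12.2 (−0.75) and rbg-2 (−0.72, SE 0.09, adjusted p = 0.00135). The call of cdk-4 ended with scaled libraries (log2 −0.88) or end events (−1.35). That of fbxa-76 ended with end events (log2 0.69, adjusted p = 0.390) or replicates 2 and 3 (0.86, 0.113), and that of fbxb-78 with scaled libraries (0.62, 0.181), end events (0.25, 0.957) or replicates 2 and 3 (0.46, 0.098). The count was 24–50 when 1 library was left out. It was 28 without wild-type replicate 3, 31 without rbm-5(n5132) replicate 1, and 30 and 26 without uaf-1(n4588) replicates 1 and 2. It was 24 and 31 without replicates 2 and 3 of the double mutant with n5119, and 28 without replicate 2 of that with n5132. The calls of clec-266, ZC262.2, gldc-1, C30F12.2 and acp-5 (log2 −0.95 without uaf-1(n4588) replicate 2) ended without single libraries. Over all alternatives the log2 change was 0.71 to 0.88 for clec-266 and 0.42 to 0.65 for ZC262.2. It was −1.77 to −1.41 for gldc-1 and −0.87 to −0.67 for C30F12.2. Calls of sna-3, fbxc-25, fbxa-143, H11L12.1 and rbg-2 held in 25 of 25 alternatives. Both sna-3 and amdh-1 lie on the chromosome of uaf-1, and no alternative tests a linked sequence variant.

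Among the gene lists, maternal and oocyte transcripts were higher in uaf-1(n4588) than in wild type. Of 29 tested members 25 were higher, with a median log2 change of 1.16. Among all genes 0 were called, and 6 when adjusted over the list alone (adjusted p = 1.7e-11, and adjusted p = 0.89 with an estimated correlation). Examples are the eggshell chondroitin proteoglycan gene cpg-2 (12.8 ± 6.9 to 68.6 ± 15 FPKM, log2 2.46, SE 0.51), the chitin synthase gene chs-1 (2.41 to 10.1 FPKM, log2 1.7), the yolk receptor gene rme-2 (2.65 to 15.2 FPKM) and the egg membrane gene egg-2 (3.85 to 12.8 FPKM). Germline nuclear and helicase genes had a median of 0.75, with 16 of 19 higher (adjusted p = 4.04e-05, and adjusted p = 0.993 with an estimated correlation). Examples are glh-1, a Vasa helicase (11.25 and 24.9 FPKM), and syp-2, a synaptonemal complex gene (22.5 and 49.5 FPKM). Within wild type the maternal list averaged −1.50 in replicate 1, 0.07 in replicate 2 and −0.45 in replicate 3, as log2 deviations from the mean of all libraries.

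The other lists did not pass in this contrast. Median log2 changes were −0.21 for 5 targets tied to these alleles (adjusted p = 0.65), −0.06 for 25 core spliceosome genes (0.54), 0.00 for 18 splicing regulators (0.82), −0.23 for 8 nonsense-mediated decay factors (0.78) and 0.16 for 7 genes with natural decay isoforms (0.93). They were 0.40 for 4 cytosolic heat shock genes (0.62), −0.25 for 10 unfolded protein response genes (0.29), 0.21 for 21 early zygotic genes (0.17), 0.03 for 16 cell death genes (0.85), 0.13 for 33 ribosomal protein genes (0.45) and 0.04 for 12 immunity and xenobiotic genes (0.63). Tissue lists had medians of −0.30 for body wall muscle (adjusted p = 0.074), −0.29 for pharynx (0.41), −0.42 for intestine (0.093), −0.25 for epidermis and cuticle (0.29), −0.24 for the nervous system (0.35) and −0.23 for hatching and first larval stage genes (0.68). Sperm and adult transcripts (median −0.04, adjusted p = 0.96) were testable only with n5119 in the uaf-1(n4588) background, and histones, 3 genes each time, in contrasts with n5132 (lowest adjusted p = 0.27).

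The rbm-5 single mutants were compared with wild type to ask what RBM-5 does when U2AF is intact. No splicing event passed in either allele. The exon of efa-6, an Arf6 exchange factor (IV:12611800–12611952), had the smallest p with n5119 and was included at a share of 1 in each wild-type library, 0.646 ± 0.11 in rbm-5(n5119) (log2 −4.75, SE 0.77, adjusted p = 0.0756) and 0.780 ± 0.097 in rbm-5(n5132) (log2 −3.80, SE 0.77, adjusted p = 0.339). Averaged over alleles and backgrounds it was the 1 event called (log2 −3.16, SE 0.48, adjusted p = 0.0265), although libraries overlapped. Other values with n5119 were a plc-1 donor form (X:10807964–10808102, 0 to 0.525 ± 0.1), an exon of the phosphatase gene cdc-14 (0.350 ± 0.1 to 0) and an exon of the engulfment receptor gene ced-1 (0.724 ± 0.053 to 1), each with an adjusted p of 0.359. With n5132, a short exon of the AMP deaminase gene ampd-1 (II:5204670–5204705) was at 0.504 ± 0.17 in wild type and 0 in each mutant library (adjusted p = 0.279), and a donor form of F14D7.6 at 0.131 ± 0.12 and 0.789 ± 0.19 (adjusted p = 0.757). Limma called 0 of 3083 events with n5119 (164, or 5.32%, at an unadjusted p under 0.05) and 0 of 3141 with n5132 (138, or 4.39%). Without rbm-5(n5119) replicate 1 the first count was 11, and with replicates 2 and 3 it was 13. The second was 7 without rbm-5(n5132) replicate 3, 3 without wild-type replicate 1 or 2, and 5 with replicates 2 and 3.

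In expression, rbm-5(n5119) had 2 of 8757 genes called, both lower (474 at an unadjusted p under 0.05). F26F2.5 was at 32.8 and 22.3 FPKM in wild type and Y45G12B.3 at 41.8 and 16.45 FPKM, and both were listed at 0 in the mutant libraries that list them (adjusted p = 0.0223 and 0.0141). The count was 0 without wild-type replicate 3 and 5 without rbm-5(n5119) replicate 1. The median change over all tested genes was −0.22, so lists are given beside it. Pharynx (median −1.24, 15 of 16 lower), hatching and first larval stage genes (−0.92, 13 of 14 lower), body wall muscle (−0.69, 22 of 23 lower) and nervous system (−0.67, 29 of 33 lower) were low. Their adjusted p were 0.013, 0.0363, 0.0425 and 0.0259, and 0 members were called. Maternal (0.46), germline (0.35), nonsense-mediated decay factor (0.32), early zygotic (0.21) and core spliceosome genes were high (adjusted p from 4.04e-05 to 0.0213), the last with a median of 0.17 but a mean of −0.19. Of these 9 lists the decay factors could not be run with an estimated correlation, and the other 8 had an adjusted p = 0.993 with an estimated correlation. All 4 low lists were low mainly in replicate 3 of rbm-5(n5119): −1.97 for pharynx, −1.53 for hatching, −1.46 for body wall muscle and −1.42 for nervous system, against −0.24 to 0.32 in replicates 1 and 2. The high lists also lean on that library, with 0.52 for maternal, 0.61 for germline, 0.50 for decay factors, 0.31 for early zygotic and 0.46 for core spliceosome genes, against −0.68 to 0.25 in replicates 1 and 2. In rbm-5(n5132), F02E9.5 was the 1 gene called of 8777 (log2 2.93, adjusted p = 0.00234, 414 at an unadjusted p under 0.05), a call lost with end events. The count was 3 without wild-type replicate 1, 2 without wild-type replicate 2 or rbm-5(n5132) replicate 2. It was 0 without wild-type replicate 3 or rbm-5(n5132) replicate 3. Maternal genes were high (median 0.93, 26 of 27, 4 adjusted over the list alone, adjusted p = 8.3e-11, and adjusted p = 0.89 with an estimated correlation). So were germline (1.06, 17 of 18, 3 adjusted over the list alone, adjusted p = 2.15e-10) and early zygotic genes (0.43, 19 of 20, adjusted p = 0.0046), the last 2 at an adjusted p = 0.993 with an estimated correlation. Wild-type replicate 1 was low on all 3 lists (−1.50, −1.05 and −0.72), against −0.46 to 0.25 in replicates 2 and 3.

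The double mutants were compared with uaf-1(n4588) to ask which of its changes an rbm-5 mutation alters. Several genes raised in uaf-1(n4588) were closer to their wild-type level in the double mutant with n5132. They were called as raised in the same uaf-1(n4588) libraries, so these contrasts are not independent. Whether the n5132 allele or another difference between the strains is the source was not tested. Y37E3.30 fell from 301 ± 11 to 56.1 ± 0.77 FPKM (log2 −2.40, SE 0.34, adjusted p = 0.022), E01G4.5 from 292 ± 36 (n = 2) to 55.6 ± 12 FPKM (log2 −2.39, SE 0.33, adjusted p = 0.0277) and linc-8 from 121 ± 49 to 31.9 ± 7.3 FPKM (log2 −1.85, SE 0.28, adjusted p = 0.0395). With n5119 the same genes stood at 259 ± 95, 296 ± 40 (n = 2) and 89.5 ± 24 FPKM. The other 4 of 7 called genes, C07D10.6, ikb-1, Y45G12B.3 and F23D12.7, had a strain listed at 0, and for ikb-1 end events reversed the direction (log2 −8.29). In all, 2 genes were higher and 5 lower of 8158, with 604 at an unadjusted p under 0.05 and all 7 with libraries that did not overlap (chance 10%). The count was 2 without uaf-1(n4588) replicate 1 or double-mutant replicate 2 or 3, and 4 without double-mutant replicate 1. It was 2 with the replicate number as a block and 3 in the fit of the contrast's own libraries. The E01G4.5 call ended without any 1 double-mutant replicate (log2 −2.52 to −2.22). That of Y37E3.30 ended without any of 5 libraries (−2.43 to −2.38) and that of linc-8 without any of 6 (−2.02 to −1.53).

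In splicing, 1 of 3294 events passed with n5132 (166 at an unadjusted p under 0.05): the donor form of pph-4.2, at 0.587 ± 0.28 in uaf-1(n4588), was at 1 in each double-mutant library, as in wild type (log2 5.87, SE 0.89, adjusted p = 0.0354). The call ended without uaf-1(n4588) replicate 1 (log2 4.88) or double-mutant replicate 2 or 3 (both 5.68). The count was 0, 4 and 2 without uaf-1(n4588) replicate 1, 3 and 2. With n5119 the same form was also at 1 in each library (log2 5.31, SE 0.89, adjusted p = 0.0891), and limma called 0 of 3323 events (137 at an unadjusted p under 0.05). The donor form of gon-14 (V:6607505–6607983) was at 0.384 ± 0.11 in uaf-1(n4588) and 0 in each library with n5119 (adjusted p = 0.0891), and an exon of nrfl-1 (IV:9120195–9120266) at 0 and 0.320 ± 0.1 (adjusted p = 0.324). In expression with n5119, the noncoding RNA C38D9.13 (V:17573208–17574227) was higher, at 12.8, 10.1 and 20.7 FPKM against 0.647, 0 and 1.28 (log2 3.26, adjusted p = 0.01), with the call lost without uaf-1(n4588) replicate 2 (log2 2.94). K10D2.5 was at 131 and 103 FPKM in uaf-1(n4588) and listed at 0 in the double mutant (adjusted p = 0.01). These were the 2 called of 8358 (396 at an unadjusted p under 0.05), and the count was 1 and 5 without uaf-1(n4588) replicates 2 and 3.

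Core spliceosome genes passed as higher in each double mutant against uaf-1(n4588), but these contrasts share the uaf-1(n4588) libraries and are not independent. The median was 0.23 with n5119 (21 of 26 higher, adjusted p = 0.00037, over a median of all genes of −0.13) and 0.27 with n5132 (19 of 26, 1 adjusted over the list alone, adjusted p = 0.00339). Both had an adjusted p = 0.993 with an estimated correlation. Over 46 members the list averaged 0.27, −0.22 and −0.20 in the uaf-1(n4588) libraries and −0.15 to 0.20 in those of the double mutants, so the strains overlap. Among them were the U2 snRNP gene sftb-1 (72.4 to 131 FPKM with n5132, log2 0.85, SE 0.21) and uaf-1 itself (log2 0.85, SE 0.25, adjusted p = 0.457). Early zygotic genes were higher (medians 0.37 and 0.53, adjusted p = 0.02 and 0.0328, and adjusted p = 0.993 with an estimated correlation for both). With n5132, ribosomal protein genes were lower (median −0.77, 25 of 28, adjusted p = 5.09e-05) and maternal transcripts lower (median −0.30, 17 of 27, 3 adjusted over the list alone, adjusted p = 0.0259), each with an adjusted p = 0.993 with an estimated correlation. The ribosomal list averaged 0.44, −1.04 and −0.77 in replicates 1, 2 and 3 of that double mutant. Against rbm-5(n5132), the same double mutant also had lower ribosomal protein genes (median −0.56, 30 of 33, 2 adjusted over the list alone, adjusted p = 0.000143) and germline genes (−0.46, 15 of 19, adjusted p = 0.0249, but 0.106 with the replicate number as a block), both at an adjusted p = 0.993 with an estimated correlation. Against rbm-5(n5119), no list passed in the other double mutant.

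The interaction asks directly whether the effect of uaf-1(n4588) differs when rbm-5 is mutated. For splicing, limma called 0 of 2654 events with n5119 (88 at an unadjusted p under 0.05) and 0 of 2669 with n5132 (100), with all adjusted p at 1. The smallest p belonged to a donor form of dlk-1 (log2 −3.09), an unannotated intron of uaf-1 (−9.94) and the pph-4.2 form (4.87) with n5119, and to pph-4.2 (4.89), T23G7.2 (−3.77) and sup-26 (2.95) with n5132. Without rbm-5(n5119) replicate 1, 6 events were called with n5119. Across the 13 events called in wild type, the effect in the rbm-5 mutant had a slope of 0.783 with n5119 and 0.751 with n5132 on the effect in wild type, and all 13 kept their sign in both. The pph-4.2 form kept only the sign, at log2 −0.047 and −0.034 (SE 0.89 for both), with a share of 1 in each double-mutant library. Simulated data with equal effects gave 0.763–1.02 and 0.773–1.01, because events chosen in 1 background look larger there. The second slope lay just below the simulated range. The pph-4.2 form, at log2 −4.92 in wild type, lowers it, and no slope was made without this form. An event called in wild type but not in the averaged contrast carried no effect in the simulated data. The range is no reference for such an event, so the second slope does not show a weaker effect with n5132. For events chosen in the other rbm-5 background, the ratio of mean effects was 1.05 over 10 events and 0.940 over 17.

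For expression the slope was 0.488 over 12 genes with n5119 (10 in the same direction, simulated 0.688–1.10) and 0.0652 over 14 genes with n5132 (8 in the same direction, simulated 0.698–1.09), both below the simulated range. Only 666 and 692 simulations had enough calls for a slope. Genes called in wild type but not in the averaged contrast carried no effect in them, so these ranges do not test equal effects of the 12 and 14 genes. For 9 genes chosen in the other background the ratio with n5132 was 0.136. Among the 9 is Y45G12B.3, listed at 0 in rbm-5(n5119) and in the double mutant with n5132. Its change therefore had opposite signs in the 2 rbm-5 backgrounds, which lowers the ratio, and no ratio was made without it. Over all tested genes, where noise in the wild-type effect lowers a slope, the alleles were closer, at 0.155 and 0.106. Both slopes lean on genes that depend on values listed at 0 or on the transcript end. Leaving out E01A2.1, ikb-1, F23D12.7 and F02E9.5, an alternative added after the data were seen, gave 0.643 with n5119 and 0.181 with n5132, for which no simulated range was made. With n5132, 6 of 7563 genes were called (1 higher, 5 lower, 349 at an unadjusted p under 0.05). In cpg-2 (III:7102092–7103990), each single mutation went with a higher level but their combination did not: 12.8 ± 6.9 FPKM in wild type, 63.3 ± 17 in rbm-5(n5132), 68.6 ± 15 in uaf-1(n4588) and 15.5 ± 7.7 in the double mutant (log2 −4.48, SE 0.71, adjusted p = 0.0271). T24D1.3 (1.96, 10.3, 12 and 2.55 FPKM, log2 −3.94) and nyn-1, an RNase-domain gene (9.80, 33.3, 23.6 and 12.2 FPKM, log2 −2.55), had the same adjusted p. E01G4.5 (log2 −3.17, adjusted p = 0.0356), F02E9.5 (−3.07) and C07D10.6 (6.96) were outside the naming rule because libraries overlapped. The count was 1 without wild-type replicate 3 or rbm-5(n5132) replicate 3, and 2 without double-mutant replicate 2 or 3. It was 3 with the replicate number as a block. Each of the cpg-2, T24D1.3, nyn-1 and E01G4.5 calls ended without wild-type replicate 3 (log2 −4.59, −3.96, −2.49 and −3.01) and without several other single libraries.

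With n5119, limma called 0 of 7695 genes for the interaction (144 at an unadjusted p under 0.05, lowest adjusted p = 0.144), and 3, 4, 1, 3, 2 and 1 without rbm-5(n5119) replicates 1 and 2, uaf-1(n4588) replicates 1 and 3, and double-mutant replicates 1 and 3. The smallest p belonged to C38D9.13 (log2 3.65), Y45G12B.3, K10D2.5, K06A5.2 (log2 6.48) and F15D4.5 (log2 3.01). The interactions share the wild-type and uaf-1(n4588) libraries, so their likeness between alleles is no evidence by itself, and wild-type replicate 1, at −1.50 on the maternal list, pushes both down. Maternal transcripts had medians of −0.74 over 27 genes (24 lower, adjusted p = 9.14e-08, over a median of all genes of 0.12) and −1.44 over 26 genes (22 lower, 7 adjusted over the list alone, adjusted p = 1.78e-10). Their adjusted p with an estimated correlation was 0.993 and 0.89. Germline genes had medians of −0.66 and −1.24 (adjusted p = 0.000313 and 2.95e-06, 16 of 19 and 15 of 18 lower), and ribosomal protein genes −0.76 with n5132 (24 of 28 lower, adjusted p = 0.000443), all 3 at an adjusted p = 0.993 with an estimated correlation.

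**Figure D4:**
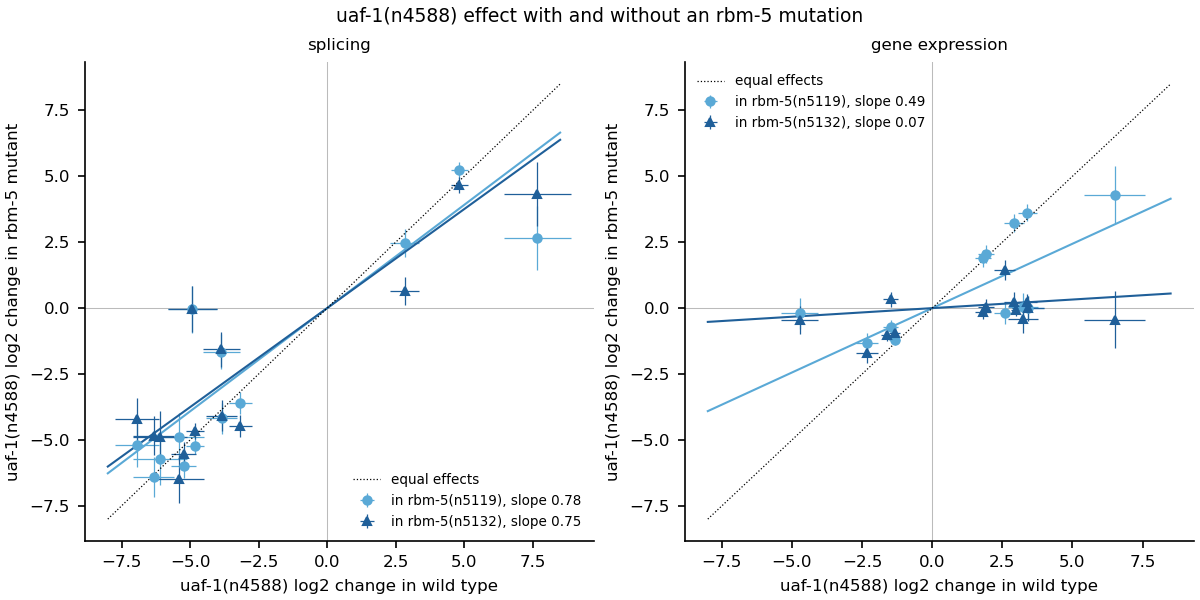
Log2 change by uaf-1(n4588) in an rbm-5 mutant (y axis) against that in wild type (x axis) for events (left) and genes (right) called in wild type, with standard errors, the fitted slopes through the origin and a dotted line of equal effects. Splicing slopes are 0.783 and 0.751, and expression slopes 0.488 with n5119 and 0.0652 with n5132.

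The rbm-5 alleles were compared with each other to see whether they act alike. Over a median of all genes of 0.26, 1 of 8840 genes was called (Y45G12B.3, listed at 0 in rbm-5(n5119), adjusted p = 0.0441, 421 at an unadjusted p under 0.05). The count was 7, 2, 6 and 2 without rbm-5(n5119) replicates 1, 2 and 3 and rbm-5(n5132) replicate 1, and the Y45G12B.3 call ended without any 1 rbm-5(n5132) library. Limma called 0 of 3075 events (4.62% at an unadjusted p under 0.05, lowest adjusted p = 0.178), and 9 without rbm-5(n5119) replicate 1 and 4 without rbm-5(n5132) replicate 3. An exon of lea-1 (V:10025535–10025711) was at 0 in rbm-5(n5119) and 0.330 ± 0.07 in rbm-5(n5132), and the ampd-1 exon at 0.399 ± 0.26 and 0. Core spliceosome genes passed with a median of −0.04 and a mean of 0.39, which differ in sign (adjusted p = 0.0425, and adjusted p = 0.993 with an estimated correlation). Averaged over alleles and backgrounds, rbm-5 mutations changed 2 of 7160 genes (659 at an unadjusted p under 0.05), both with strains listed at 0. The interaction averaged over alleles changed 1 of 7160 genes (238 at an unadjusted p under 0.05), and limma called 0 of 2534 events for it (89).

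Libraries of strains with uaf-1(n4588) listed more alternative splicing events. They held 1585 ± 65.6 skipped exons per library against 1447 ± 57.5 in the others (n = 9 each, 139 more, exact permutation p = 0.0005, adjusted p = 0.00175) and 2541 ± 118.8 alternative exon ends against 2305 ± 132 (236 more, exact permutation p = 0.00025, adjusted p = 0.00175). Transcript ends were fewer (20447 ± 175 against 20688 ± 180, adjusted p = 0.0461 by the exact permutation test), a difference of −240 that was −258, −270 and −193 without replicate 1, 2 or 3 (adjusted p = 0.108, 0.0648 and 0.324, with fewer permutations to be had). At FPKM of at least 1 it was −86.2 and did not pass, and per 1000 start events it passed (−6.71, adjusted p = 0.0005). Retained introns numbered 2075 ± 154 and 2079 ± 146 (adjusted p = 0.965 by the exact permutation test). Without the libraries of replicate 3, the differences were 128 skipped exons and 184 alternative exon ends, both at an adjusted p of 0.0648. No event type differed with rbm-5 mutations (12 libraries against 6, lowest adjusted p = 0.768). Transcripts were assembled separately in each library at an unknown depth, and what this does to the listed counts was not tested. The libraries with uaf-1(n4588) also held more loci that no reference gene names (1158 against 979, exact permutation p = 0.0005).

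**Figure D5:**
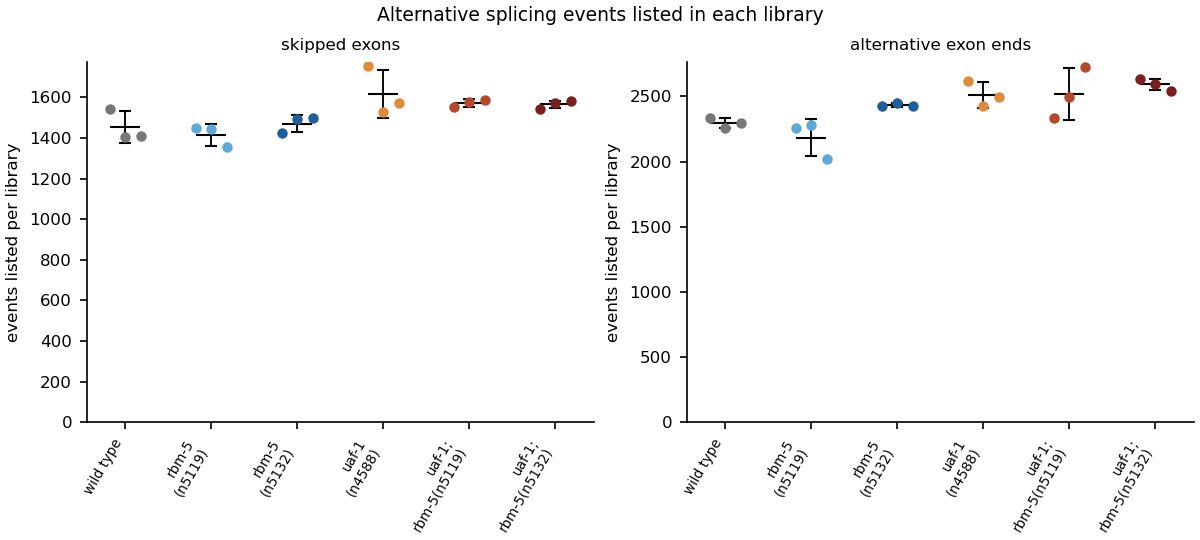
Number of skipped exons (left) and alternative exon ends (right) listed per library (points, y axis from 0) in the 6 strains (x axis), with the mean (long line) and standard deviation. Strains with uaf-1(n4588) average 1585 skipped exons and 2541 alternative exon ends, and the others 1447 and 2305.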

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

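Of the tests below, those of the 3 weighed patterns, the averaged contrasts and the counts over other splits of the libraries were chosen only after the results were seen.

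The uaf-1(n4588) effect on 6 genes differed between wild type and rbm-5(n5132) by the interaction test. The log2 difference was −4.48 for the eggshell gene cpg-2, −3.94 for T24D1.3, −2.55 for nyn-1, −3.17 for E01G4.5, −3.07 for F02E9.5 and 6.96 for C07D10.6. F02E9.5 depends on start events, and C07D10.6 is at 0 in the start events of every other strain, but its end events reach 348 FPKM in 1 uaf-1(n4588) library and 421 FPKM in the double mutant with n5119. Among gene lists, the interaction had a median of −0.74 for maternal and oocyte genes and −0.66 for germline genes with n5119. With n5132 the medians were −1.445 for maternal and oocyte genes, −1.24 for germline genes and −0.76 for ribosomal protein genes. The 2 interactions share libraries, none of these lists passed with an estimated correlation, and differences in the age of the collected embryos were not tested.

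A signal also appeared in data outside the comparisons, the loci that no reference gene names. Libraries with uaf-1(n4588) held 1158 ± 77.8 such loci and the others 979 ± 84.4 (n = 9 each). The difference was 179 (exact permutation p = 0.0005). Loci that merge genes also made up more of the libraries, 8.40 ± 0.856% against 7.32 ± 0.749% (exact permutation p = 0.019). Gene levels leave such loci out, and what this does to the expression results was not tested.

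The first pattern weighed is the set of 71 splicing events called for uaf-1(n4588) averaged over 3 backgrounds. For the unusual replicate 1 libraries, the effect in replicates 2 and 3 was a median of 0.997 times that in all replicates (0.735–1.33). This shows only that the called effects were also present in replicates 2 and 3. It cannot exclude replicate 1 as a source, since calls needed a small spread within strains and all replicates include replicates 2 and 3. A sequence variant linked to uaf-1 on chromosome III that acts in cis on these genes is argued against, since 11.27% of the events lie there, against 15.5% of tested events. A change in expression of the same genes is argued against for most of the 59 events whose gene was tested, since the gene's change plus 2 SE reached the event's change in 5.085% of them. An effect of uaf-1(n4588) on splicing may be the source, a hypothesis found and tested on the same data, but a linked variant that acts on other genes, and variants elsewhere in the strains, stay open.

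The next pattern is the 9 called genes with a strain listed at 0. For F02E9.5 that strain took no part in the contrasts above that called it. Its value of 0 does not bear on those calls, although the gene is counted here. Failed estimates where neighbouring genes are joined in 1 locus may explain part of them, since 66.67% either lost the call with the larger of start and end events or shared a locus name with another gene. The former were C07D10.6, C44B12.6 and F02E9.5, and the latter F23D12.7, K10D2.5 and ikb-1 (3 of 9, where 12.4–18.01% of all genes share a name in a strain). Low expression stays open: the median in the other strains was 27.55 FPKM, but a call needs a high level there, and C44B12.6 was at 1.13 FPKM. No biological explanation was tested for the remaining 3.

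The last pattern is the concentration of FPKM in replicate 1 libraries. Gene length bias stays open: the difference in log2 ratio between genes under 500 bases and longer genes ranged from −0.181 to 1.199 over the 6 strains. A few genes taking most of the counts are argued against as the whole cause, because 5 strains stayed over 20% higher without their 10 highest start events. No biological explanation was tested, since the labels name no difference between replicates.

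For contrasts of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real count of genes and the highest of the other splits were 14 and 2 for uaf-1(n4588) (1 of 10 splits as large), 2 and 4 for rbm-5(n5119) (3 of 10) and 1 and 2 for rbm-5(n5132) (7 of 10), each against wild type. Against uaf-1(n4588) they were 2 and 3 with n5119 (3 of 10) and 7 and 4 with n5132 (1 of 10). Against the rbm-5 single mutants they were 10 and 6 (1 of 10) and 2 and 3 (6 of 10), and between the alleles 1 and 2 (7 of 10). For splicing, in the same order, they were 13 and 0 (1 of 10), 0 and 3, 0 and 4, and 0 and 2 (10 of 10 each), 1 and 2 (3 of 10), 18 and 3 (1 of 10), 10 and 4 (1 of 10), and 0 and 3 (10 of 10). Where the real count is 0, every split is as large by definition, so 10 of 10 there tells nothing about chance.

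For the other contrasts 100 splits were drawn. For uaf-1(n4588) averaged over backgrounds there were 47 genes against at most 8 and 71 events against at most 15 (1 of 100 splits each). Chance can be excluded for each of these counts only when taken alone. A share of 1 of 100 is the smallest that 100 splits can give, and it was not adjusted over 26 counts. For the interaction with n5132 in expression, with 6 genes and a highest other of 6 (2 of 100), chance can likewise be excluded only for this count taken alone, without adjustment over 26 counts. That count was 1 without wild-type replicate 3 and 3 with the replicate number as a block. Chance cannot be excluded for rbm-5 mutations averaged (2 genes against 10, 23 of 100, and 1 event against 4, 33 of 100) or for the averaged interaction in expression (1 gene, 60 of 100). In the latter, 1 other split called 370 genes, which points to a structure of the samples, and what that structure is was not tested. A real count of 0 is matched by all 100 splits by definition, which decides nothing. This holds for the interaction with n5119 (0 genes against 3, and 0 events against 6), for events with n5132 (0 against 4) and for events of the averaged interaction (0 against 6).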

How the results depend on the processing

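Replicates 2 and 3 alone, gene levels from end events or from the larger of start and end events, every alternative of the averaged contrasts, items chosen in the other rbm-5 background, slopes without 4 genes and the preset correlation on complete genes were chosen only after the data were seen. Of the results that answer a comparison, 356 alternatives stayed close (224 of them leaving out libraries) and 202 moved. Close means within 1.5 times for counts, the same direction and side of the threshold for listed events, and within 1 jackknife SE for slopes, which have no threshold. For named genes and events 1417 alternatives kept the call and 371 ended it. Where fewer libraries or other filters change what is tested, counts move by construction, and otherwise the cause was not tested.

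Below, contrasts follow 1 order: uaf-1(n4588), n5119 and n5132 against wild type, n5119 and n5132 doubles against uaf-1(n4588), then against their rbm-5 mutants, the interactions with n5119 and n5132, n5132 against n5119, and the averaged uaf-1(n4588), rbm-5 and interaction. Called genes were 14, 2, 1, 2, 7, 10, 2, 0, 6, 1, 47, 2 and 1. Leaving out 1 library gave 3–15, 0–5, 0–3, 1–5, 2–6, 3–11, 2–5, 0–4, 1–9, 1–7, 24–50, 0–5 and 0–6. Called events were 13, 0, 0, 0, 1, 18, 10, 0, 0, 0, 71, 1 and 0, and leaving out 1 library gave 10–19, 0–11, 0–7, 0–1, 0–4, 14–28, 9–18, 0–6, 0–2, 0–9, 54–69, 0–5 and 0–1. A group left with 2 libraries shares the pooled spread.

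Libraries scaled to the same median gave 9 genes for uaf-1(n4588), 2 for n5132, 5 for the n5119 double against uaf-1(n4588), 1 and 2 for the interactions, 5 for the averaged rbm-5 mutations and 2 for the averaged interaction. A pseudocount of 0.1 FPKM gave 2 genes for n5132, 4 for the n5119 double against uaf-1(n4588), 3 for the interaction with n5119, 2 between alleles, and 4 and 2 for the averaged rbm-5 mutations and interaction. It gave 1 and 2 events for the doubles against uaf-1(n4588) and 2 and 2 for the averaged rbm-5 mutations and interaction. No filter on low FPKM gave 0 genes for n5119, 2 for n5132, 27 for the n5132 double against uaf-1(n4588), 16 and 31 for the doubles against rbm-5 mutants, 16 for the interaction with n5132, 0 between alleles, 3 for the averaged interaction, and 0 events for the n5132 double against uaf-1(n4588).

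End events gave 0 genes for n5132, 4 for the n5119 double against uaf-1(n4588), 1 for the n5132 double against rbm-5(n5132) and 1 for the interaction with n5119. The larger of start and end events gave 0, 7, 1 and 1. For ikb-1 both settings reversed the change, to 7.62 and 7.62 in uaf-1(n4588) against wild type, and to −8.29 and −8.15 in the n5132 double against uaf-1(n4588), since its end events are high where its start events are listed at 0.

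No label says what the replicate numbers stand for. Of 45 pairs of libraries with the same number, 21 had deviations correlated above 0.1, with a median of 0.0866 and a range of −0.359 to 0.414. As a hint from the data, 13 of 18 libraries correlated best with their own number, so a shared batch stays open. As a block the numbers gave 6 genes for uaf-1(n4588), 0 for n5119, 0 for n5132, 1 and 2 for the doubles against uaf-1(n4588), 6 and 1 against rbm-5 mutants, 3 for the interaction with n5132, 0 between alleles and 1 for the averaged rbm-5 mutations. They gave 1 event each for the n5119 double against uaf-1(n4588) and the averaged interaction. A fit of the contrast's libraries alone gave 6 genes for uaf-1(n4588), 0 for n5119, 2 for n5132, 0 and 3 for the doubles against uaf-1(n4588), 0 for the n5119 double against rbm-5(n5119) and 6 between alleles. It gave 22, 3, 3, 6 and 3 events for the first 5 contrasts, 26 for the n5132 double against rbm-5(n5132), 1 for the interaction with n5119 and 3 between alleles.

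Replicates 2 and 3 alone gave 9, 8, 6 and 4 genes for the first 4 contrasts, 17 and 23 for the doubles against rbm-5 mutants, 5 and 18 for the interactions, 10 between alleles, and 5 and 10 for the averaged rbm-5 mutations and interaction. Of the 9 for uaf-1(n4588), 3 were shared with the 14. They gave 31, 13, 5, 6, 5, 33 and 19 events for the first 7 contrasts, 9 and 4 for the interactions, 12 between alleles, and 5 and 3 for the averaged rbm-5 mutations and interaction.

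For listed events, leaving out a replicate number changed the uaf-1(n4588) difference to 128–153 skipped exons (139), 15.7–27.3 exon groups (21.9), −56 to 48.8 retained introns (−3.22), 6.33–16.17 intron groups (11.9), 184.0–265 alternative exon ends (236), −120 to −83.0 starts (−99.7) and −270 to −193 ends (−240). The end difference ended without each replicate number, and those in skipped exons and alternative exon ends without replicate 3. Per 1000 start events, the end difference passed (−6.71, adjusted p = 0.0005), as did exon groups (1.081, adjusted p = 0.0491), and retained introns reversed (0.289). At FPKM of at least 1, the end difference was −86.2 and did not pass. For rbm-5 mutations the ranges were −70.4 to 33.6 (−29.3), −32.5 to 4.63 (−18.2), 0 to 18 (10.8), 6 to 15.9 (11.9), −15.1 to 74.5 (28.6), −90.8 to −16.12 (−41.4) and −24.6 to 22.8 (0.667), and at FPKM of at least 1 retained introns reversed to −19.4 and ends to −384.5.

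Splicing slopes were 0.743–0.819 and 0.721–0.785 with 1 library left out, 0.238 and 0.274 over all tested events, where noise in the wild-type effect lowers a slope, and 1.05 and 0.940 as ratios for events chosen in the other background. Expression slopes were 0.419–0.683 and 0.0312–0.0987 with 1 library left out, 0.155 and 0.106 over all tested genes, 0.136 as a ratio with n5132, and 0.643 and 0.181 leaving out E01A2.1, ikb-1, F23D12.7 and F02E9.5. Of 194 list and contrast pairs, 28 passed with the preset correlation, 18 on genes listed in all 18 libraries, 17 with the block, 0 with an estimated correlation and 0 with fry. The planned analysis of 3′ splice sites was not run for want of a genome sequence. Depth limits could not be given, because FPKM values hold no counts.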

Other observations

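Tests of acceptors and of F-box genes below were chosen only after the result was seen, and that of the rbm-5 alleles was written beforehand.

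Because U2AF recognises 3′ splice sites, acceptor choice may respond to uaf-1(n4588) more often than donor choice. In the averaged contrast, 13 of 218 genes with a tested alternative acceptor had a called one (5.96%), against 4 of 310 genes for donors (1.29%, Fisher's exact p = 0.0044). Genes are not independent samples, and the 3′ splice site sequences themselves were not examined.

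F-box genes may rise together in strains with uaf-1(n4588). Of 98 tested F-box genes 75 were higher and 23 lower, with a mean averaged log2 change of 0.28. The 6 called genes prompted the test, so it was run on the other 92, whose mean was 0.23: the real split was the only 1 of 100 with a mean as far from 0, and the highest other was 0.203. What links these genes to U2AF was not tested.

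If the 2 rbm-5 alleles act on the same events, their effects should correlate. Between pairs of contrasts that share no library, Pearson's r across 2534 events was 0.0536 and 0.0587 (Spearman's 0.0413 and 0.0648). For the former, 44 of 100 splits lay as far from 0, with a highest other of 0.203, so a weak shared effect could lie within the other splits. For comparison, r between uaf-1(n4588) effects in wild type and in an rbm-5 mutant was 0.248 with n5119 and 0.280 with n5132 (adjusted p = 0.08 for both over 8 relations, by splits), and events are not independent.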
